A study of Mus musculus with 12 samples.

How the data were processed

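Gene expression was measured in the livers of 12 male mice on Affymetrix mouse arrays. Of these, 6 lacked Pctp and 6 were wild-type littermates, and all had eaten 0.2% fenofibrate for 7 days. Per the labels' protocols, total RNA was labelled as biotinylated cRNA and each liver was put on an array of its own. The feeding state and the time of day at collection are not given in the sources used here.

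The intensity values, 1 per probe set and array, were deposited by the authors on a linear scale after summarising the probes and scaling the arrays. The program that did this is not given in the sources used here. The authors also deposited a table of 727 selected probe sets, whose intensity columns match the value table within 0.005. Per the file headers, it gives the authors' group means with standard errors and a signed fold with its bounds. It also gives, per the file headers, a score (the t statistic), an unadjusted p-value, and the percent of arrays with a present call in each group. The test behind the p-value and the detection method are not given in the sources used here. Its 12 columns of detection calls per array were not used here. Its fold, the lower bound of the fold, p-value and percent of present calls were only set beside the results.

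The arrays had median intensities from 84 to 91.1. Correlations between arrays on the log2 scale ran from 0.985 to 0.994, and 0 pairs of arrays had identical values. The number of arrays limits the precision. Of the probe sets, 64 controls were left out and 22626 were tested. Of these, 20380 had 1 gene symbol, 691 several and 1555 none. A gene was represented by its probe set with the highest mean, which gave 12393 genes. Chromosomes and positions came from a reference gene table of the assembly GRCm38.p6.

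Values were analysed as log2(intensity + 16), knockout minus wild type, with the scaling as deposited. Each probe set was tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Means and SD of intensity are on the linear scale, and folds are 2 to the power of the log2 difference, so they include the added 16. Single measures, such as a ratio of control probe sets, were compared by two-sided exact permutation tests. Gene lists with at least 5 measured genes were tested with camera of limma at a preset correlation of 0.01. Its p-values were adjusted over the 25 pathway lists and the 14 cell type lists separately. Camera with an estimated correlation was run beside it, as was fry, which tests whether a list's genes move on balance in 1 direction and does not compare them with other genes.

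The tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule names Pctp, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, and, in each pathway list, up to 2 genes with the smallest p past the threshold. It gave 59 genes, 29 higher and 30 lower. Other genes are named only as chosen after their values were seen. These are Ppara, the Pctp neighbours Acaca and Pdk2, and the members given for the cell type lists. Also among them are the members given for 6 lists of genes that were themselves chosen after the data were seen. A clock score, the mean of standardised values of 5 clock genes minus that of 5 genes of opposite phase, and the beta-actin ratio served as covariates in alternatives that were also chosen after the data were seen.

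The alternatives were other added constants (1 and 64), a filter on dim probe sets, quantile normalization, median centring, a trended and robust variance model, array weights, an unmoderated test, the replicate number as a block, leaving out each array, other thresholds, and the mean of a gene's probe sets in the list tests. Ranges of adjusted p over the alternatives of a gene leave out the fits without 1 array and those with the beta-actin ratio. Splits of the arrays were drawn at random, 100 with the real one. The procedure was tested on simulated data of 6 and 6 arrays with 200 changed probe sets. It recovered 69% of changes of 0.5 and 99% of changes of 1 on the log2 scale, with 4.55% false calls, and called the shifted list and 0 of 24 others. The simulated probe sets were drawn independently of each other. The simulation therefore does not show how the list test behaves when genes of a list vary together, as in the real arrays. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.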

Results

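The series asks what phosphatidylcholine transfer protein (PC-TP, also called StarD2, the product of Pctp) does to the liver's response to activation of the nuclear receptor PPARα. PC-TP binds phosphatidylcholine and moves it between membranes. Fenofibrate is a lipid-lowering drug that activates PPARα. Liver RNA was measured on 12 Affymetrix mouse arrays, each hybridised with RNA from a different animal. The animals were male mice on an FVB background, 6 lacking Pctp and 6 wild-type littermates. Both groups ate a diet with 0.2% fenofibrate for 7 days from 8 weeks of age, and the livers were taken at 9 weeks. The number of arrays limits the precision of each comparison. The median intensity per array lay between 84 and 91.1 in the authors' units. No group on a diet without fenofibrate was analysed here, so each difference is one between genotypes under the drug.

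Pctp itself was almost gone from the knockout livers. Its brighter probe set had an intensity of 82.5 ± 12.3 (SD, n = 6) in knockout and 2855 ± 77.2 (SD, n = 6) in wild-type livers, a ratio of 34.6. No arrays overlapped: the knockout values ran from 66.5 to 99.7 and the wild-type values from 2737 to 2954. On the log2(intensity + 16) scale the difference, knockout minus wild type, was -4.87 (SE 0.0744, adjusted p = 3.37e-13, limma). A two-sided exact permutation test over all assignments of the arrays to groups of this size gave p = 0.00216, the smallest it can give. Its other probe set read 21.0 ± 9.46 in knockout and 1213 ± 97.3 in wild type (SD, n = 6 each). The authors' deposited table gives a fold of -34.88 for the brighter probe set, with a present call on 66% of the knockout arrays and 100% of the wild-type arrays. Pctp lies on chromosome 11 from 89982544 to 90002894 in the assembly GRCm38.p6. Which part of the gene is disrupted, and whether the probes lie in it, is not given in the sources used here.

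**Figure D1:**
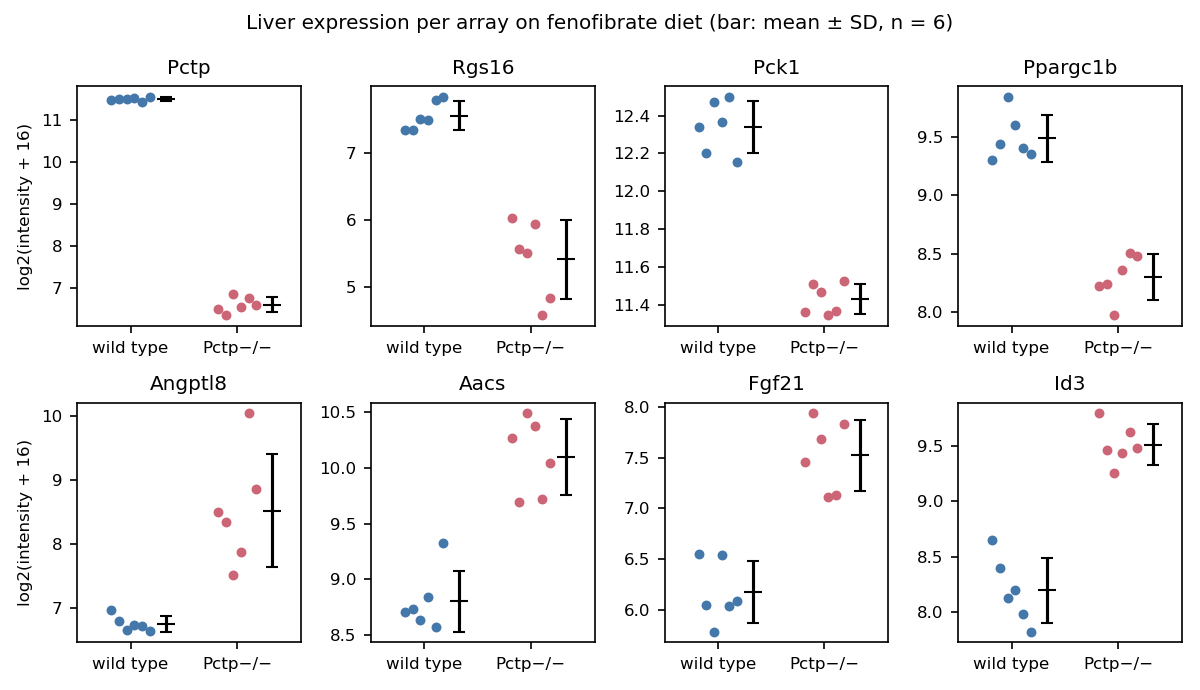
Expression of 8 genes per array as log2(intensity + 16), where each point is 1 liver and the bar gives the mean ± SD of 6 livers. Wild-type and knockout points do not overlap for any of these genes, with log2 differences from -4.87 for Pctp to 1.78 for Angptl8.

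Of 22626 probe sets, 2708 (12%) differed between the genotypes at an adjusted p under 0.05, those of Pctp included. Of these 2708, 1543 were higher and 1165 lower in the knockout. Counting each gene once, 798 genes rose and 646 fell among 12393. Most of these changes were small. The median absolute log2 difference of the 1444 genes was 0.31, and 136 of them changed by at least 1.5-fold, 65 upward and 71 downward. The 2 groups did not overlap at all for 840 genes (6.78%), where chance gives 0.216%. The first principal component held 27.3% of the variance and separated the genotypes, with knockout arrays between -19.2 and -12.0 and wild-type arrays between 7.45 and 22.8. The split into higher and lower calls depended on scaling: 57.0% of the calls were higher as deposited, 49.2% after quantile normalization and 44.0% after centring each array on its median.

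The control probe sets that report RNA integrity also differed between the groups. For beta-actin, the log2 ratio of the 5' to the 3' probe set was -1.19 ± 0.0846 in knockout and -1.58 ± 0.134 in wild type (SD, n = 6 each), without overlap. This difference of 0.39 had p = 0.00216 by a two-sided exact permutation test (0.00289 after Benjamini-Hochberg adjustment over 4 transcripts). The ratios of Gapdh and pyruvate carboxylase were higher in knockout by 0.11 and 0.33, each with an exact permutation p of 0.00216 (adjusted 0.00289), while that of the transferrin receptor differed by 0.07 (exact permutation p = 0.652). With the beta-actin ratio as a covariate, a setting chosen after seeing the data, 2 probe sets stayed past the threshold, both of Pctp, while 1507 had an unadjusted p under 0.05 against 5949 without the covariate. In that fit the median absolute difference of the 2708 probe sets went from 0.32 to 0.20 and the median SE grew by a factor of 2.06. As the groups share no ratio, calls of genes and lists kept or lost in it, Pctp aside, do not separate RNA integrity from genotype.

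**Figure D2:**
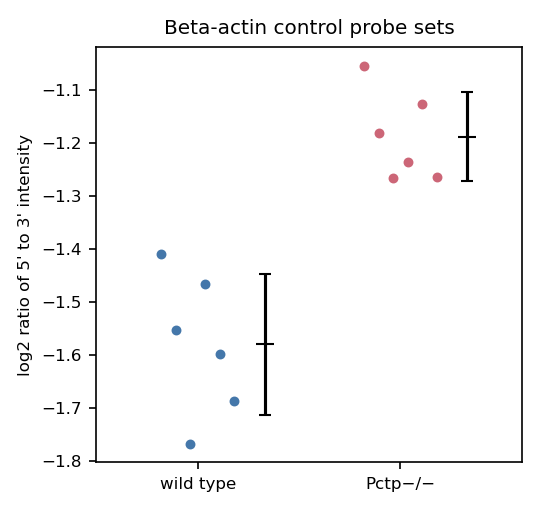
Log2 ratio of the 5' to the 3' beta-actin control probe set on each array, with the mean ± SD of 6 arrays per genotype. The knockout arrays lie between -1.27 and -1.05 and the wild-type arrays between -1.77 and -1.41.

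Genes are ranked here by their brightest probe set on the log2(intensity + 16) scale, and the order depends on both choices. Zbtb16, a zinc-finger transcription factor, fell 4.54-fold by that probe set, from an intensity of 304.2 ± 128 to 51.7 ± 21.1 (SD, n = 6 each, adjusted p = 0.00234), while its other probe set was at 0.07 on the log2 scale and did not pass. Rgs16, which shortens G-protein signals, fell 4.39-fold (adjusted p = 0.000334), with its 3 probe sets all past the threshold at 1.85-fold to 6.34-fold. Mycl fell 3.76-fold and Retnla 2.89-fold, both without overlap between groups. Other probe sets of Mycl fell less, 1.49-fold (adjusted p = 0.00903) and 1.18-fold (adjusted p = 0.0909, not past the threshold). The metallothionein Mt2 fell 2.84-fold (adjusted p = 0.0163), with overlap between groups, and the uridine phosphorylase Upp2 fell 2.53-fold (adjusted p = 0.00506). Folds are on the log2(intensity + 16) scale, which understates those of dim genes such as Retnla, at 20.6 ± 12.9 in knockout.

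Ranked in the same way, the largest rise was in Angptl8, a secreted inhibitor of lipoprotein lipase, from 91.4 ± 9.14 to 420.5 ± 318 (SD, n = 6 each), or 3.42-fold (adjusted p = 0.00483). Knockout replicate 5 read 1037.57 and the other knockout arrays between 166.26 and 449, so its size and rank lean on 1 array. The hormone gene Fgf21, a known PPARα target, rose 2.54-fold (adjusted p = 0.0008), and the transcriptional regulator Id3 rose 2.48-fold (adjusted p = 0.000218). The stress-inducible chaperone Hspa1a rose 2.91-fold (adjusted p = 0.0177), Jun 2.22-fold (adjusted p = 0.00428) and Nr0b2, which encodes the nuclear receptor SHP, 2.29-fold (adjusted p = 0.0122). Genes that interferon induces were among the largest rises, with Ifi47 at 3.10-fold (adjusted p = 0.0395), Irgm1 at 2.99-fold (adjusted p = 0.0321) and Cxcl10 at 2.76-fold (adjusted p = 0.0124). Their groups overlapped. The calls of Ifi47 and Irgm1 were lost when any 1 of knockout replicates 1, 2, 4 and 6 or wild-type replicates 1, 3, 4 and 5 was left out, with adjusted p from 0.0671 to 0.0833 and from 0.0553 to 0.0705. Other alternatives ended them too, among them the unmoderated test (adjusted p = 0.0766 and 0.0653) and the clock score as a covariate (adjusted p = 0.0925 and 0.0758). With the beta-actin ratio as a covariate, Nr0b2 was at -0.11 (adjusted p = 0.983), against a range from 0.00506 to 0.0298 over its other alternatives.

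PPARα raises genes of fatty acid oxidation. In peroxisomal fatty acid oxidation 3 of 29 measured genes rose and none fell, among them the transporter Abcd2 (1.41-fold, adjusted p = 0.00465) and Hacl1 (1.26-fold, adjusted p = 0.00689). In mitochondrial fatty acid oxidation 3 of 22 rose, including Acot2 (1.28-fold, adjusted p = 0.00246) and Etfdh (1.19-fold, adjusted p = 0.0048), and 2 fell. Of 16 genes of fatty acid omega-oxidation and acyl-CoA hydrolysis, Acot12 was the 1 that rose (1.19-fold), and Acot7 (1.20-fold) was among the 2 that fell. Of 7 ketone body genes, Fgf21 was the 1 that rose. Among 36 other PPARα responsive genes 4 rose, such as the glycerol channel Aqp3 (1.48-fold, adjusted p = 0.00438), and 3 fell, such as Lpin2 (1.23-fold, adjusted p = 0.0139). Camera passed none of these 5 lists, with adjusted p of 0.155, 0.828, 0.606, 0.606 and 0.647. Ppara, singled out after its value was seen, fell by 0.44 on the log2 scale (SE 0.0786, adjusted p = 0.00449).

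Of 21 measured genes of cholesterol synthesis 10 rose and none fell, with a median log2 difference of 0.19. Aacs, which makes acetoacetyl-CoA in the cytosol for lipid synthesis, rose 2.45-fold, from 437.7 ± 95.6 to 1104 ± 254 (SD, n = 6 each, adjusted p = 0.000694). Hsd17b7 rose 1.5-fold (adjusted p = 0.00455). The set test gave an adjusted p of 3.52e-05, and with an estimated correlation between genes (0.52) the adjusted p = 0.619. The list kept its call with the beta-actin ratio as a covariate (adjusted p = 0.000145). The groups share no such ratio, so that fit does not separate RNA integrity from genotype. Fatty acid synthesis genes went both ways: of 23, Mid1ip1 (1.91-fold, adjusted p = 0.000616) and the transcription factor gene Srebf1 (1.6-fold, adjusted p = 0.00159) rose, 2 fell, and the list did not pass (adjusted p = 0.606).

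Pck1, which encodes the cytosolic PEPCK of gluconeogenesis, fell 1.88-fold, from 5182 ± 496 to 2743 ± 151 (SD, n = 6 each, adjusted p = 2.46e-05). The coactivator gene Ppargc1a fell 2.43-fold (adjusted p = 0.0119), in all 5 of its probe sets. The size of its fall leans on wild-type replicates 3 and 5, at 193.82 and 232.98, where the other wild-type arrays lay between 54.64 and 104.8. In the list of gluconeogenesis, glycolysis and insulin signalling 8 of 42 genes fell and 3 rose, with an adjusted p of 0.0319 for a downward shift. That call was lost with an estimated correlation (adjusted p = 0.397), after quantile normalization (adjusted p = 0.0826), among the brighter probe sets (0.198), and without knockout replicate 1 (0.0532) or 4 (0.0613). With the beta-actin ratio as a covariate, which moved with genotype by 0.39, the adjusted p was 0.744.

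Of 50 genes of amino acid breakdown and the urea cycle 13 fell and none rose. Got1, a cytosolic transaminase, fell 2.36-fold (adjusted p = 0.0195), with overlap between groups. Its wild-type replicates 3 and 5 read 1304.68 and 1271.1 and the other wild-type arrays between 392.77 and 559.83, so the size of the fall leans on those replicates. The ornithine carrier gene Slc25a15 fell 1.38-fold (adjusted p = 0.00314) and Hgd, of tyrosine breakdown, 1.21-fold (adjusted p = 0.00367). The set test gave an adjusted p of 0.000681, an adjusted p = 0.397 with an estimated correlation, and an adjusted p of 0.744 with the beta-actin ratio as a covariate.

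Among 43 nuclear receptors and cofactors 12 fell and 4 rose. The coactivator gene Ppargc1b fell 2.28-fold (adjusted p = 0.000112) and Lpin1, both a coactivator and a phosphatidate phosphatase, 2.34-fold (adjusted p = 0.00194). In the circadian clock list 6 of 23 genes fell and none rose, led by Cry2 (1.42-fold, adjusted p = 0.00201) and Per1 (1.68-fold, adjusted p = 0.00289). Neither list passed camera (adjusted p of 0.13 each), while fry called both downward (adjusted p = 0.00872 and adjusted p = 0.0126). The median of the nuclear receptor list was 0.00, and -0.03 after quantile normalization or median centring. The unfolded protein and amino acid stress list (36 genes, 4 higher, 7 lower, adjusted p = 0.0965) held Atf4, up 1.52-fold, and the chaperone Hyou1, down 1.39-fold. The heat shock and oxidative stress list (30 genes, 4 higher, 6 lower, adjusted p = 0.72) held the transcription factor gene Nfe2l2, up 1.86-fold (adjusted p = 0.000791), and Hspb1, down 1.59-fold (adjusted p = 0.00134).

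PC-TP is itself a lipid transfer protein with a START domain. Of 27 phospholipid and methyl-group genes only Ptdss1 passed, up 1.12-fold (adjusted p = 0.0183). That call was lost after median centring (adjusted p = 0.0765) and with the replicate block (adjusted p = 0.0686), with 0.004 as the lowest over its alternatives. Among 29 START-domain and other lipid transfer genes 3 rose, including the phosphatidylinositol transfer protein gene Pitpnb (1.71-fold, adjusted p = 0.00155), whose other 2 probe sets did not pass, and 6 fell. These opposite changes cancel in a directional set test. In triacylglycerol metabolism 3 of 20 fell, Lpin1 and Lpin2 among them. In bile acid metabolism 2 of 28 rose and 3 fell, with the sterol transporter gene Abcg8 down 1.66-fold (adjusted p = 0.00261) and Cyp39a1 down 1.31-fold. Of 26 lipoprotein genes 2 rose and 3 fell, with Apom down 1.33-fold (adjusted p = 0.00216). The adjusted p of these 5 lists were 0.83, 0.828, 0.219, 0.584 and 0.512.

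Of 64 xenobiotic genes 6 fell and none rose, led by Cyp2j6 (1.37-fold) and Cyp1a2 (1.23-fold). Of 45 growth hormone dependent genes 3 rose and 2 fell, the latter being the complement gene C9 (1.82-fold, adjusted p = 0.000129) and Hsd3b2 (1.38-fold). Of 38 acute phase genes 3 fell, Mt2 and Orm3 (1.16-fold) among them. Of 51 cell cycle genes 3 rose, with Cdk4 at 1.18-fold and Plk1 at 1.28-fold, and 2 fell. In oxidative phosphorylation 1 of 71 rose, Sdhd at 1.15-fold, and 2 fell, with Cox7a1 down 1.5-fold. Of 42 ribosomal protein genes 3 rose, with Rpl7a at 1.12-fold and Rps3 at 1.10-fold, whose call was also lost after median centring (adjusted p = 0.0932, with alternatives from 0.00213 to 0.107). Of 32 extracellular matrix genes 3 rose, including Dcn at 1.23-fold, and 1 fell, Col4a1 at 1.36-fold. None of these 7 lists passed camera, with adjusted p of 0.13, 0.647, 0.3, 0.647, 0.134, 0.268 and 0.606. Leaving out 1 array ended the calls of Cox7a1 (knockout replicates 1, 2, 3, 4 and 6, wild-type 2, 4 and 5, adjusted p 0.0553 to 0.0695), Plk1 (knockout 1, 2, 3 and 5, wild-type 3, 5 and 6, 0.0640 to 0.0705) and Rps3 (knockout 1, 2 and 3, wild-type 3, 5 and 6, 0.0528 to 0.0634). Plk1 was at -0.07 with the beta-actin ratio as a covariate (adjusted p = 0.967, against 0.0143 to 0.0782 over its other alternatives).

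Counts adjusted over the list alone were higher for several lists. They were 12 rising genes for cholesterol synthesis, 5 rising and 11 falling for gluconeogenesis, glycolysis and insulin signalling, 1 rising and 17 falling for amino acid breakdown, and 8 rising and 13 falling for nuclear receptors. They were 3 and 4 for omega-oxidation, 6 and 4 for other PPARα genes, 3 and 2 for fatty acid synthesis, 4 and 5 for lipoproteins, and 3 and 6 for the clock. They were 6 and 3 for the cell cycle, 4 and 13 for the unfolded protein response, and 5 and 6 for heat shock. For oxidative phosphorylation (1 and 0) and ribosomal proteins (1 and 0) they were lower, and for the other 11 pathway lists they were the same. With an estimated correlation none of the 25 pathway lists passed, although 2 had an unadjusted p under 0.05, and fry called 8. Besides the 3 lists that camera called, these were peroxisomal fatty acid oxidation upward, ribosomal proteins upward (median 0.031, but -0.0014 after median centring), and triacylglycerol metabolism, nuclear receptors and the clock downward.

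**Figure D3:**
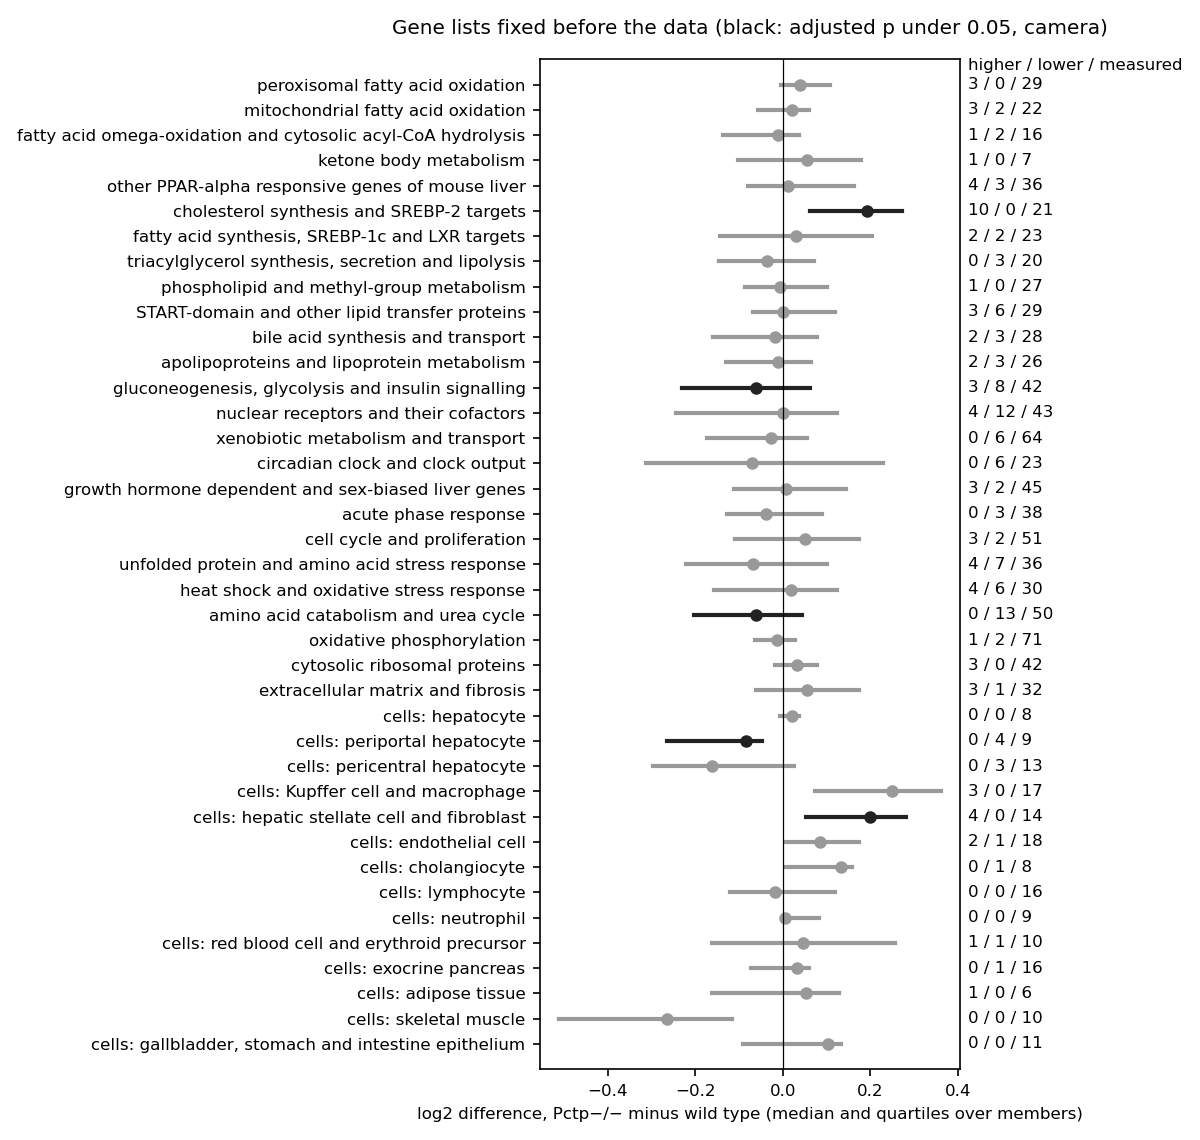
Log2 difference, knockout minus wild type, as the median (point) and quartiles (bar) over the measured genes of each list, with the number of genes higher, lower and measured. The lists past the set test, in black, are cholesterol synthesis (median 0.19), gluconeogenesis (-0.06), amino acid catabolism (-0.06), periportal hepatocytes (-0.08) and stellate cells (0.20), of which periportal hepatocytes alone pass with an estimated correlation (adjusted p = 0.04997, the others 0.619, 0.397, 0.397 and 0.484).

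Markers of cell types that a piece of liver could hold differed for some types. Of 9 periportal hepatocyte markers 4 fell and none rose: Pck1, Aldh1b1, Hal and Cps1, which act in gluconeogenesis, aldehyde oxidation, histidine breakdown and the urea cycle. The list had an adjusted p of 0.00379 and kept its call with an estimated correlation (adjusted p = 0.04997). It also kept it with the beta-actin ratio as a covariate (adjusted p = 0.0121), a fit that does not separate RNA integrity from genotype. Of its 9 genes, 5 also belong to a pathway list. Of 14 stellate cell and fibroblast markers 4 rose (7 adjusted over the list alone) and none fell, with a median of 0.20 and an adjusted p of 0.0185. That call was lost with an estimated correlation (adjusted p = 0.484), among the brighter probe sets (0.0794), without knockout replicate 1 (0.0769) or wild-type replicate 6 (0.0641), and with the clock score (0.0753) or the beta-actin ratio (0.769) as a covariate. The risen markers were Ecm1, Dcn, Rgs5 and Reln, while the collagen markers Col1a1 and Col3a1 were at -0.01 and -0.07 and did not pass. The cell type markers given here were singled out after their values were seen.

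The remaining cell type lists did not pass camera. Of 13 pericentral markers 3 fell (median -0.16, adjusted p = 0.0765), and fry called that list downward (adjusted p = 0.0337), as it did the periportal list (adjusted p = 3.61e-05). Of 17 Kupffer cell and macrophage markers 3 rose (median 0.25, adjusted p = 0.14). Of 18 endothelial markers 2 rose and 1 fell (4 and 2 adjusted over the list alone, adjusted p = 0.251). Among 8 cholangiocyte markers 1 fell, among 10 red blood cell markers 1 rose and 1 fell, among 16 pancreas markers 1 fell and among 6 adipose markers 1 rose, with adjusted p of 0.886, 0.886, 0.886 and 0.941. No marker of hepatocytes (8), lymphocytes (16), neutrophils (9), skeletal muscle (10) or gallbladder, stomach and intestine (11) passed. The median of the muscle list was -0.26 (adjusted p = 0.109). Leaving out 1 array called some further lists. These were the unfolded protein list (without knockout replicate 2 or wild-type replicate 3, 5 or 6, adjusted p from 0.0301 to 0.0426) and oxidative phosphorylation (without wild-type replicate 2, 0.0281). Among cell types they were pericentral (without knockout replicate 3 or wild-type replicate 3, 0.0274 and 0.0326), Kupffer (without wild-type replicate 2 or 5, 0.0152 and 0.00953) and muscle markers (without wild-type replicate 2 or 3, 0.0349 and 0.0452).

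The authors' deposited table lists 727 probe sets, 414 higher and 313 lower in knockout. Of these, 718 passed the threshold here in the same direction and 9 did not. All 727 had the same sign, while 1990 probe sets called here are not in that table. The smallest absolute fold in the table is 1.28 and the largest p-value of the authors is 0.0472.

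Among the named genes, 24 had more than 1 probe set: 10 of these passed with every probe set, and 8 with the chosen one alone (Zbtb16, Acot12, Pitpnb, Pck1, Cdk4, Hyou1, Slc25a15 and Col4a1). The other probe set of Pck1 was dim, at 14.6 in wild type and 15.6 in knockout. Those of Acot12 (1100 in wild type, 1089 in knockout) and Col4a1 (546 and 522) were bright and did not pass. Single alternatives also ended the calls of Orm3 (adjusted p up to 0.105), Hspa1a (0.0784), Rpl7a (0.0592), Col4a1 (0.0551) and Dcn (0.0552). The unmoderated test and the clock score each ended the calls of Plk1 (adjusted p up to 0.0782) and Cox7a1 (up to 0.0843).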

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

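The tests of RNA integrity, linked DNA and other splits of the arrays were chosen only after the results were seen, while the search for stray arrays was fixed beforehand. Among the named genes, the beta-actin ratio and the clock score, 5 of 122 groups of 6 arrays held an array far from the others by Dixon's test of the gap against the range, and chance gives about 1 in 20. Aacs was at an intensity of 625.41 in wild-type replicate 6, where the other wild-type arrays lay between 365 and 443. Hacl1 was at 3976.1 in wild-type replicate 1 (others 3327 to 3516) and Cdk4 at 454.45 in wild-type replicate 5 (others 386 to 399). Acot7 was at 538.53 in knockout replicate 1 (others 628 to 678) and Apom at 1407.48 in knockout replicate 6 (others 1593 to 1631). These 5 genes kept their calls when any 1 array was left out.

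The ratios of 5' to 3' control probe sets, which are outside the gene comparison, differed between genotypes by 0.39 for beta-actin, 0.11 for Gapdh and 0.33 for pyruvate carboxylase on the log2 scale, each without overlap of the groups. A lower ratio is a sign of degraded or incompletely copied RNA. The wild-type arrays had the lower ratios, so RNA quality and genotype go together in these 12 arrays. Whether the genotypes were extracted, labelled or hybridised in separate batches is not given in the sources used here. Such a batch could not be told apart from genotype either.

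With 2708 probe sets differing between genotypes, a difference in RNA integrity could account for part of them. With the beta-actin ratio as a covariate the median absolute difference of these probe sets went from 0.32 to 0.20, and 2532 of 2708 kept their sign. The retained share was 0.631 (95% interval 0.609 to 0.658). That interval reflects the spread over probe sets, so it does not give the uncertainty over livers. Calls ended for all but 2 probe sets, both because differences shrank and because the SE grew by a factor of 2.06. As no knockout array shared a ratio with a wild-type array, the effects of RNA integrity and of genotype cannot be told apart for these probe sets, except for the fall of Pctp. An effect of the genotype on RNA quality, or on the transcripts themselves, stays open.

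DNA linked to the disrupted allele could also differ between the groups. Of the 2507 called probe sets with a known chromosome, 90.5% lay off chromosome 11, so most calls are not differences within linked genes themselves. The share of all tested probe sets on chromosome 11 was not set beside this. The 90.5% therefore does not show whether that chromosome holds more calls than its share. Position cannot tell an effect of linked DNA on genes elsewhere from an effect of losing Pctp, so that possibility stays open. Among the 50 genes on each side of Pctp, 11 of 100 passed against 11.7% of the other genes (odds ratio 0.937, 95% interval 0.45 to 1.76, Fisher's exact p = 1). Linked DNA also stays open for single neighbours, since with a fold of at least 1.5, 3% of these 100 passed against 1.08% (odds ratio 2.84, 95% interval 0.569 to 8.74, Fisher's exact p = 0.0961). With 100 genes on each side it was 2.5% against 1.07% (odds ratio 2.37, 95% interval 0.75 to 5.78, Fisher's exact p = 0.068). Acaca, of the fatty acid synthesis list, lay within 50 genes of Pctp and fell by 0.61 on the log2 scale (adjusted p = 0.00451, limma). So did Pdk2, of the gluconeogenesis list, by 0.24 (adjusted p = 0.0216, limma). Linked DNA stays open for these list members.

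Chance can be excluded as the source of the number of probe sets: of 100 splits of the 12 arrays, 1, the real one, gave as many as 2708, and the highest other gave 15. The same held for 1543 higher and 1165 lower probe sets (1 of 100 each, highest other 15). It cannot be excluded for the number of lists. As many as 3 pathway lists passed in 44 of 100 splits (highest other 8), and as many as 2 cell type lists in 46 of 100 (highest other 5). Which lists passed in those splits was not compared.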

How the results depend on the processing

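Alternatives with a covariate were chosen only after the result was seen, and the others before the data were examined. Pctp kept its direction and call in every alternative run, from -4.92 to -4.83 when any 1 array was left out. The 2708 differing probe sets numbered 2402 with log2(intensity + 1), 3234 with + 64, 3071 among brighter probe sets, 2831 after quantile normalization, 2786 after median centring, 3128 with a trended and robust variance, 2771 with array weights, 2611 without moderation and 2469 without chromosome 11. The list tests were not run with the trended variance, without moderation or with a fold threshold.

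By construction, other thresholds gave other counts: 2315 higher at 0.1; 970 differing, 573 higher, 397 lower and 1 cell type list at 0.01; and 278, 140 and 138 with a fold of at least 1.5. Counted as genes there were 1444, and the authors selected 727.

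Leaving out 1 array gave 2006 to 2742 differing, 1132 to 1641 higher and 855 to 1101 lower probe sets, 2 to 4 pathway lists, 1 to 4 cell type lists and 54 to 58 named genes. Cell type lists numbered 1 without knockout replicate 1 or wild-type replicate 6, and 4 without wild-type replicate 2 or 3.

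For the lists, the mean of all probe sets gave 5 pathway and 4 cell type lists, an estimated correlation 0 and 1, and fry 8 and 3. Cell type lists numbered 1 among brighter probe sets and 1 with the clock score as a covariate, which gave 1019 higher probe sets. The cause was not tested.

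With the beta-actin ratio as a covariate, 2 probe sets differed, 0 higher and 2 lower, and of the named genes 1 passed (Pctp). Of the lists, cholesterol synthesis (adjusted p = 0.000145) and periportal hepatocytes (adjusted p = 0.0121) kept their calls, and gluconeogenesis, amino acid breakdown and stellate cells lost theirs. Others were called instead: the unfolded protein response downward (adjusted p = 6e-05), ribosomal proteins upward (adjusted p = 0.0276) and skeletal muscle downward (adjusted p = 0.0019), so that 3 pathway and 2 cell type lists passed. Nr0b2 (-0.11) and Plk1 (-0.071) reversed without passing, and the other 56 named genes kept their direction. The SE grew because the ratio goes with genotype. No knockout array shared a ratio with a wild-type array. Calls kept, lost or gained in this fit, Pctp aside, therefore do not show whether RNA integrity is their source.

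With the replicate block, 1906 probe sets differed, 1179 higher and 727 lower, and 53 named genes passed. Of the lists, the block added pericentral hepatocytes (adjusted p = 0.0484) and the clock score the unfolded protein response (adjusted p = 0.0215). Over all probe sets, correlations of same-numbered arrays lay between -0.078 and 0.078, and 0 of 6 knockout arrays correlated best with their own number. The clock score, however, rose with the replicate number in knockout, from -2.28 (replicate 1) to 1.44 (replicate 6). In wild type it rose from -1.17 (replicate 1) to 1.48 (replicate 6), with replicate 5 out of order. A shared order behind the numbers is therefore not excluded. Of the 58 named genes besides Pctp, calls were lost for 6 with the block, 6 with the clock score, 4 without moderation, 3 with the trended variance, 2 after median centring and 1 with log2(intensity + 1).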

Other observations

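The tests of Per1, Cry2 and the lists fixed before the data are repeated here from the results above. Their use here to weigh clock phase and feeding state was chosen only after the results were seen. The other tests in this part and its 6 gene lists were also chosen only then, so their p-values are no independent evidence. Of 49 genes of the nucleolus and ribosome assembly 24 were higher in knockout and none lower, with a median log2 difference of 0.23 and, with an estimated correlation, an adjusted p = 0.0295 (camera of limma, over 6 lists). Ltv1 (0.59) and Nop58 (0.54) were among them. Of 34 interferon response genes 7 were higher (median 0.46), of 35 splicing factors 10 were higher and 3 lower (median 0.07), and of 36 immediate early genes 7 were higher and 2 lower (median 0.14). These 3 lists passed at the preset correlation (adjusted p = 0.000255, adjusted p = 0.0119 and adjusted p = 0.0189) and did not with an estimated one (adjusted p = 0.383 each).

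Of 40 genes that fasting, glucagon or glucocorticoid raises in mouse liver, 17 were lower in knockout and 1 higher (median -0.28). Of 27 genes that feeding or insulin raises, 10 were higher and 2 lower (median 0.18). Both lists passed with an estimated correlation (adjusted p = 0.0339 each), but 25 and 20 of their genes also belong to the lists in the report, and they were drawn up after the calls were seen. The score of the feeding list minus the fasting list was 0.94 ± 0.105 in knockout and 0.18 ± 0.212 in wild type (SD, n = 6 each), a difference of 0.76 (SE 0.0965). As the lists hold genes already seen to differ, this separation is not a test of the pattern.

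With the clock score as a covariate the difference was 0.78 (SE 0.108). This argues only against clock phase, as that score measures it, as the whole source of this pattern. The clock score leaves out Per1 and Cry2, which fell (adjusted p = 0.00289 and 0.00201, limma), so a clock difference outside its genes stays open. The clock score itself was -0.44 ± 1.54 in knockout and 0.44 ± 0.945 in wild type (SD, n = 6 each, exact permutation p = 0.253). A difference in RNA integrity could contribute: with the beta-actin ratio as a covariate the difference was 0.55 (SE 0.205), but the groups share no ratio, so the 2 cannot be told apart. A difference in feeding state at collection may also be the source, and the 4 lists fixed before the data that bear on it do not decide it. At the preset correlation 3 of them moved as feeding moves them, cholesterol synthesis upward (adjusted p = 3.52e-05), gluconeogenesis downward (adjusted p = 0.0319) and amino acid breakdown downward (adjusted p = 0.000681). With an estimated correlation none of these 3 passed (adjusted p = 0.619, adjusted p = 0.397 and adjusted p = 0.397). The fatty acid synthesis list had a median log2 difference of 0.031 and passed neither way. An effect of Pctp on these genes was not tested apart from feeding state and RNA integrity, which would need livers collected at a known feeding state and with matched RNA integrity.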
